A study of Homo sapiens with 16 samples.

How the data were processed

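The authors deposited 16 Affymetrix arrays of HepG2 cells, 4 for each combination of adenovirus (LacZ or GPI-PLD) and time (6 h or 12 h), with 10 microgram of RNA per array per the labels. The values are MAS5 signals on a linear intensity scale, per the submitters' processing notes, and the deposited signals had a 2% trimmed mean of 1000.3 to 1000.4 in every array. The scanner and any other processing steps were not given in the sources used here. Replicates were numbered here in deposited order, because the labels give no replicate numbers and no batches. Nothing in the labels says whether the arrays of a group came from separate cultures, so p-values measure the spread between these samples. All columns of values were used.

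The table held 22283 probe sets, 68 of them controls. A single gene symbol belonged to 19065 probe sets, several symbols to 1043 and none to 2107, giving 11963 genes. Gene IDs of 19053 probe sets were found in a current gene table, which changed 0 symbols. The lowest and highest array medians were 304.5 and 377.6, a ratio of 1.24, so no rescaling was applied (the rule set 1.5 as the limit). No value was missing or at or below 0.

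Signals were analysed as log2(signal + 63), where 63 is the 20th percentile of all signals. Each gene was read by its probe set with 1 symbol and the highest mean, and tested if that mean reached the 40th percentile of probe sets (signal 188), which left 8102 genes. Limma (version 3.58.1, with statmod 1.5.0, in R 4.3.3) fitted the 4 groups with lmFit, contrasts.fit and eBayes with trend and robust, with 12 residual and a median of 10.5 prior degrees of freedom. The 6 contrasts were the virus effect at 6 h, at 12 h and averaged, its difference between the times, and the time effect in each virus. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. Error values after log2 differences are standard errors, and errors after signals are standard deviations. GPLD1 was tested in a fit of all 22215 probe sets outside the controls.

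Camera with a preset correlation of 0.01 tested 38 gene lists with at least 5 tested genes, adjusted over the lists of a contrast. The same test with an estimated correlation was the alternative. Lists held 1366 symbols, of which 1152 were on the array, and were fixed before the data were examined. Endothelial and erythroid markers had too few tested genes. Tables were read with Python 3.11.15, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

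Genes were named by a rule. GPLD1 came first. For each virus contrast at 1 time the 12 genes up and 12 down with the largest change were named, and for each other contrast 8 and 8, among genes that passed, with arrays that did not overlap and a mean signal at or above the median. Where fewer than 5 genes passed, the 10 with the smallest p were named. In each called list, and in the GPI and lipid lists, the rule chose the 4 members with the smallest p, of which only some are given below. For cell type markers it chose the 2 brightest. With time 467 genes in LacZ and 622 in GPI-PLD cells met the rule. A few further members of called lists were named as well. The averaged virus effect of 1 gene that met the rule is not reported here, and not every list member was given where its call was lost in several alternatives.

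Alternatives were quantile normalization, scaling to the 75th percentile, no pseudocount and 4 times the pseudocount, no filter and a filter at the 60th percentile. Further ones were the mean of a gene's probe sets, all probe sets, eBayes without trend and robust, array weights, only the 8 arrays compared, and each array left out in turn. Omitting GPI-PLD 12 h replicates 2 and 4 together was added after the data were seen.

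The steps were tested on simulated data for 8102 genes, of which 67, 67 and 66 carried known changes of 1.5-fold, 2-fold and 3-fold. At 6 h the virus contrast recovered 56.7% of 1.5-fold, 79.1% of 2-fold and 92.4% of 3-fold changes with 9 false calls, and the time contrast in LacZ recovered 52.2%, 70.1% and 97.0% with 15. A list shifted by 0.3 log2 was recovered with an adjusted camera p of 3.27e-18, and 0 of 37 other lists were called. The simulated genes were drawn independently, so the 0 of 37 does not show how list calls behave when genes are correlated. The recovery rates hold for the number of changed genes simulated. With fewer changed genes the adjusted p is harder to pass, so these rates do not give the recovery in the real virus contrasts.

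Array quality was checked. GPI-PLD 12 h arrays had mean correlations of 0.942 to 0.945 within their group, against 0.954 to 0.966 in the other groups. GAPDH 3' to 5' signal ratios ran from 0.864 to 1.12. The first principal component held 17.6% of the variance and separated the times. With 4 arrays against 4, an exact permutation test has 70 splits and a smallest p of 0.0286.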

Results

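The GPLD1 transcript, which encodes the GPI-PLD enzyme that one of the vectors was named for, had similar signals in HepG2 hepatoma cells given either adenovirus. Its 2 brighter probe sets passed the filter (signal 188) but stood near or below the array medians (304.5 to 377.6). On the first of them (the _at set) GPLD1 signal at 6 h was 306.8 ± 101 in LacZ cells and 249 ± 61.7 in GPI-PLD cells (mean ± SD, 4 arrays per group), a log2 difference of -0.22 ± 0.30 (SE). At 12 h the same probe set read 261.9 ± 110 and 291.4 ± 53.7, a log2 difference of 0.18 ± 0.30. The other brighter probe set (the _x_at set) gave 260.5 ± 37.7 and 284.3 ± 138 at 6 h (log2 0.02 ± 0.32) and 318.6 ± 136 and 328.3 ± 46.9 at 12 h (0.12 ± 0.32). Upper ends of the 95% intervals of the GPLD1 fold change, taken on signal + 63, were 1.32 at 6 h and 1.74 at 12 h at the _at set. At the _x_at set they were 1.61 and 1.73. With single arrays left out in turn, the difference at the _at set ranged from -0.44 (without LacZ 6 h replicate 3) to -0.11 (without GPI-PLD 6 h replicate 4) at 6 h. At 12 h it ranged from 0.02 (without LacZ 12 h replicate 3) to 0.34 (without LacZ 12 h replicate 4). Of the 3 dim GPLD1 probe sets, one had the largest difference at 6 h, with signals of 25.1 ± 14.1 in LacZ and 71.6 ± 31.3 in GPI-PLD (log2 0.60 ± 0.22). Its limma p of 0.0122 became an adjusted p of 0.9997 over 22215 probe sets, and at 12 h its log2 difference was 0.07. The upper end of its 95% interval at 6 h was 2.07-fold, and that of another dim set 2.44-fold. The other dim sets stood at 0.37 and -0.08 at 6 h and at -0.33 and -0.18 at 12 h. The labels do not state which part of GPLD1 the virus carried.

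**Figure D1:**
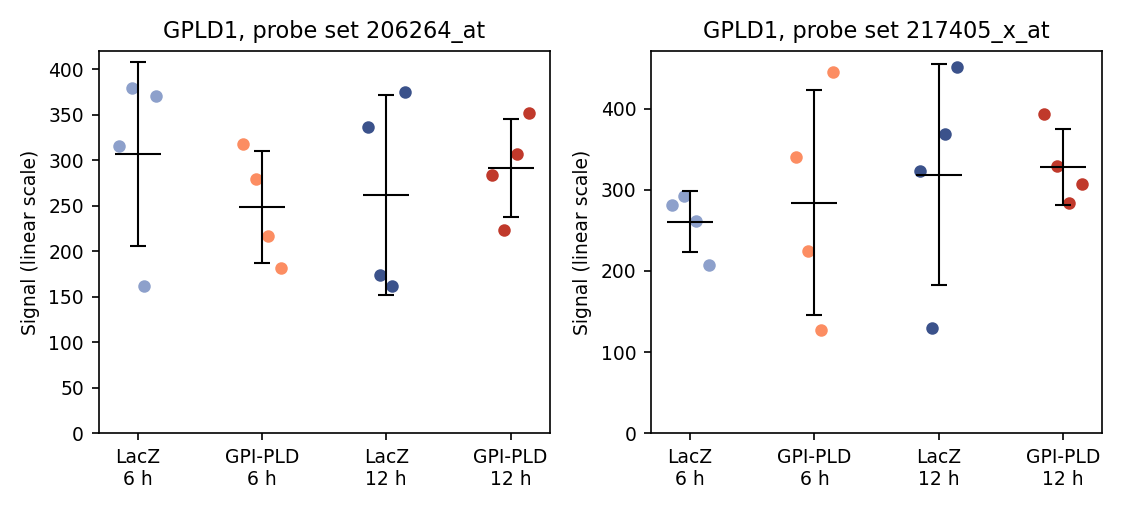
GPLD1 signal (intensity, linear axis) per array for its brighter _at (left) and _x_at (right) probe sets in LacZ and GPI-PLD cells at 6 h and 12 h, with mean ± SD of 4 arrays. On the _at set the 12 h means were 261.9 in LacZ and 291.4 in GPI-PLD cells.

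At 6 h the largest differences by p lay in DGAT1, whose enzyme performs the last step of triglyceride synthesis, and in GUCA2A and FOSL2, which encode a gut peptide hormone and an AP-1 transcription factor subunit. DGAT1 had a signal of 211 ± 126 in LacZ and 621 ± 104 in GPI-PLD cells, 2.68-fold (log2 1.42 ± 0.30, SE). GUCA2A was 2.61-fold higher (98.7 to 371; log2 1.39 ± 0.29) and FOSL2 2.52-fold higher (113 to 381; log2 1.34 ± 0.29). Another FOSL2 probe set had a smaller difference (log2 0.73 ± 0.30). HERC5, a ligase of the interferon response, was 2.77-fold lower (315 to 83; log2 -1.47 ± 0.38). None of these differences passed. The adjusted p was 0.328 for DGAT1, GUCA2A and FOSL2, and for DGAT1 it ranged from 0.0851 to 0.998 over the alternative settings. The remaining genes among the 10 with the smallest p were TPST2, a Golgi sulfotransferase (log2 0.96 ± 0.23), NAB2, a corepressor of EGR factors (1.13 ± 0.31), ANPEP, a membrane aminopeptidase (0.48 ± 0.12), TRIM28, a chromatin corepressor (0.46 ± 0.11), NPIPA1, a nuclear pore associated protein (0.46 ± 0.12), and KRT23, a keratin (-0.44 ± 0.11). Across all tested genes the limma count at 6 h was 0, with 376 genes at unadjusted p under 0.05 where 405.1 would arise by chance. The eBayes fit without trend and robust called 2, GUCA2A and FOSL2, each with an adjusted p of 0.0318.

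DGAT1 had its lowest mean in LacZ cells at 6 h. Its signal was 516 ± 133 in LacZ and 499.7 ± 203 in GPI-PLD cells at 12 h, against 620.9 in GPI-PLD cells at 6 h. In LacZ cells DGAT1 rose with time, by 2.24-fold (log2 1.16 ± 0.30, adjusted p 0.0172, range 0.00408 to 0.0695 over the alternatives). That call was lost without LacZ 6 h replicate 2 (adjusted p 0.0695) or 4 (0.0513) and without LacZ 12 h replicate 3 (0.0605) or 4 (0.0603). In GPI-PLD cells the DGAT1 difference with time was -0.34 ± 0.30.

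**Figure D2:**
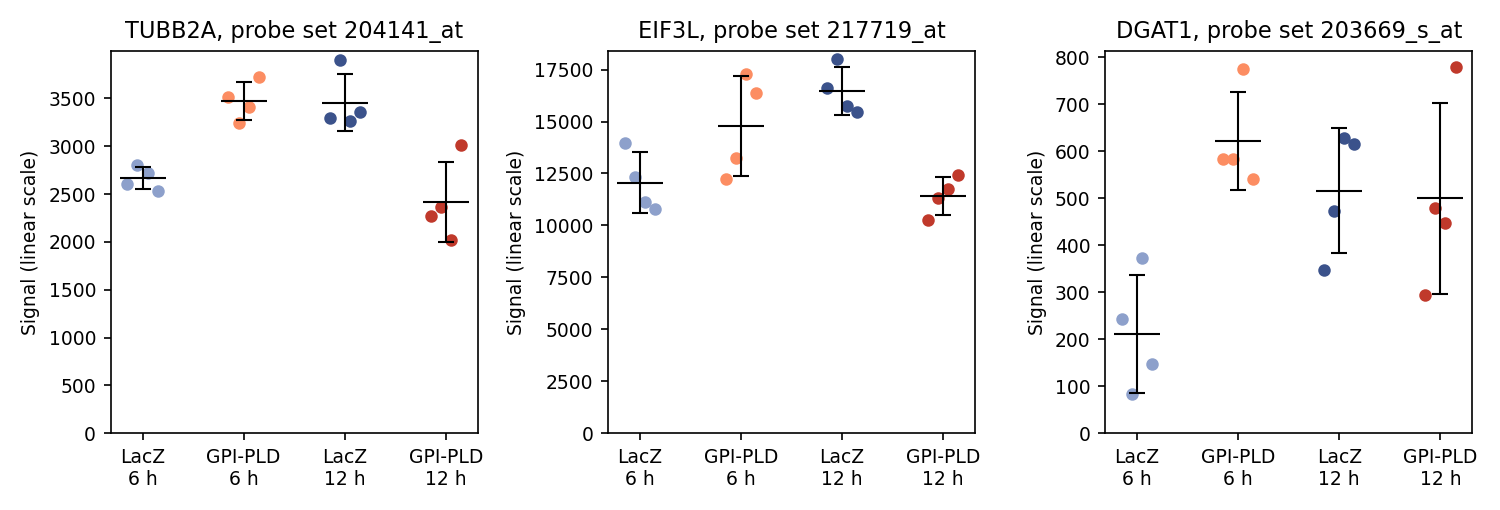
Signal (intensity, linear axis) per array of TUBB2A, EIF3L and DGAT1 in LacZ and GPI-PLD cells at 6 h and 12 h, with mean ± SD of 4 arrays. DGAT1 read 211 in LacZ cells at 6 h and 516 at 12 h.

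The fatty acid and triglyceride synthesis genes, which include DGAT1, the acetyl-CoA carboxylase gene ACACA, the fatty acid synthase gene FASN and the lipid droplet gene PNPLA3, were the 1 list called of 38 at 6 h. Of 19 tested members 16 were higher and 3 lower in GPI-PLD cells, with a median log2 difference of 0.13. Among the members, 0 passed over all genes and 1, DGAT1, rose when adjusted over the list alone. The other leading members were ACACA (0.36 ± 0.15), FASN (0.26 ± 0.14) and PNPLA3 (0.39 ± 0.28). The camera test gave an adjusted p of 0.0121 with the preset correlation, and with an estimated correlation the adjusted p was 0.0787. Leaving out LacZ 6 h replicate 2 ended the call (adjusted p 0.0787). Omitting any other 6 h array kept it, at 0.0073 to 0.0357.

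Genes of GPI anchor metabolism, the closest to the reaction of the enzyme, gave no called list between the viruses. The GPI anchor synthesis list, which covers the enzymes that build and attach the anchor, had 12 of 24 members higher at 6 h and 10 at 12 h (adjusted camera p 0.905 and 0.662). Its leading members were PGAP6, an anchor remodelling enzyme (0.35 ± 0.18 at 6 h), and PIGN, an anchor ethanolamine phosphate transferase (-1.02 ± 0.46 at 12 h). The GPI-anchored proteins, the substrates of the enzyme, had 14 of 29 higher at 6 h and 17 at 12 h (0.727 and 0.662). Among them RECK, a membrane protease inhibitor, differed by -0.54 ± 0.22 at 6 h and CD48, an adhesion receptor, by 0.70 ± 0.29 at 12 h. Triglyceride-rich lipoprotein genes gave an adjusted p of 0.226 at 6 h and 0.662 at 12 h, with CIDEB, which lipidates VLDL, at 0.38 ± 0.14 and -0.44 ± 0.14. APOC3, an inhibitor of triglyceride clearance, stood at 0.23 ± 0.12 and -0.25 ± 0.12. Of that list 0 members passed over all genes at 6 h and 1, DGAT1, rose when adjusted over the list alone. HDL genes gave 0.568 and 0.968, with the HDL receptor gene SCARB1 at 0.18 ± 0.10 at 6 h and the HDL-borne esterase gene PON3 at 0.30 ± 0.12 at 12 h. At 12 h the HDL list had a median of -0.03 but a mean of 0.01. Cholesterol synthesis genes had 14 of 17 higher at 6 h (adjusted p 0.306), led by the sterol reductase gene DHCR7 (0.22 ± 0.10), and gave 0.662 at 12 h. Phospholipid turnover genes gave 0.799 and 0.893, interferon response genes 0.322 and 0.662.

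Protein kinase C targets and immediate early genes, which respond to diacylglycerol signals, were not called either (25 tested, adjusted p 0.306 at 6 h and 0.662 at 12 h). Among them 0 passed over all genes at 6 h and 2 rose when adjusted over the list alone.

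At 12 h the genes with the smallest p were EIF3L, a subunit of translation initiation factor 3, HOXC11, a homeobox transcription factor, TUBB2A, a beta tubulin, and TFPT, a subunit of the INO80 chromatin complex. EIF3L read 16456 in LacZ and 11434 in GPI-PLD cells, 1.44-fold lower (log2 -0.52 ± 0.10, SE, 4 arrays per group). TUBB2A was 1.43-fold lower (3456 to 2416; log2 -0.52 ± 0.11) and TFPT 2.50-fold lower (441 to 144; log2 -1.32 ± 0.27). HOXC11 was higher (132 to 487; log2 1.58 ± 0.32). PLAAT2, a phospholipase and acyltransferase, was 3.74-fold higher (91 to 487; log2 1.90 ± 0.44), and KLF12, a transcriptional repressor, 2.28-fold higher (log2 1.19 ± 0.27). SSH3, a cofilin phosphatase, stood at -1.31 ± 0.31, COBLL1, an actin-binding protein, at -0.45 ± 0.11, ABAT, the GABA transaminase, at -0.46 ± 0.11, and COX7C, a cytochrome c oxidase subunit, at -0.34 ± 0.08. Other probe sets of COX7C (0.03 ± 0.13), COBLL1 (0.10 ± 0.11 and 0.17 ± 0.28) and ABAT (0.04 ± 0.10) differed in the other direction. The other SSH3 probe set had a smaller difference (-0.30 ± 0.22).

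None of the 12 h differences passed: the adjusted p was 0.159 for EIF3L, HOXC11, TUBB2A and TFPT, and for TUBB2A it ranged from 0.0181 to 0.544 over the alternatives. The limma count at 12 h was 0, with 584 genes at unadjusted p under 0.05 and 0 by the eBayes fit without trend and robust. The median 95% interval of a gene at either time reached 0.35 log2 to each side, or 1.28-fold, and 1.19-fold in the brightest part of the genes. The number of arrays, with the spread between them, limited the precision.

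Oxidative phosphorylation genes, whose products form the respiratory chain and ATP synthase, were the 1 list called at 12 h. Of 61 members 16 were higher and 45 lower in GPI-PLD cells, with a median of -0.09. Among the members, 0 passed over all genes and 1, COX7C, fell when adjusted over the list alone. Other leading members were the complex I gene NDUFB8 (-0.33 ± 0.10), the complex II gene SDHD (-0.40 ± 0.13) and the ATP synthase gene ATP5MC2 (-0.23 ± 0.09). Both other NDUFB8 probe sets differed in the other direction (0.12 ± 0.12 and 0.09 ± 0.23). The adjusted camera p was 1.78e-05 with the preset correlation, and the adjusted p with an estimated correlation was 0.255. Fatty acid and triglyceride synthesis, called at 6 h, gave an adjusted p of 0.467 at 12 h, where ELOVL6, a fatty acid elongase, stood at -0.29 ± 0.12.

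Averaged over both times, NPIPA1 had the smallest p, 1.34-fold higher in GPI-PLD cells (log2 0.42 ± 0.09, SE, 8 arrays per virus, adjusted p 0.509). STXBP5L, an inhibitor of vesicle fusion, was 2.32-fold lower (-1.21 ± 0.29) and SART3, a factor of spliceosome recycling, 1.34-fold higher (0.43 ± 0.10), while both other SART3 probe sets differed in the other direction (-0.12 ± 0.11 and -0.10 ± 0.10). TRIB3, a pseudokinase of the stress response, was 1.17-fold higher (0.23 ± 0.06). Others among the 10 smallest p were HOXC11 (0.89 ± 0.22), RBM38, an RNA-binding protein (0.40 ± 0.11), MRGBP, a subunit of a histone acetylase complex (0.33 ± 0.09), TFPT (-0.71 ± 0.19) and the pseudogene HMGB3P1 (-0.78 ± 0.21). The limma count was 0, with 340 genes at unadjusted p under 0.05 and 0 by the eBayes fit without trend and robust. Oxidative phosphorylation genes were lower as a list (45 of 61 members, median -0.03, 0 over all genes and 0 when adjusted over the list alone, adjusted camera p 0.0133). The adjusted p with an estimated correlation was 0.602, and the call was lost without LacZ 6 h replicate 3 (adjusted p 0.131), LacZ 12 h replicate 3 (0.0846) or GPI-PLD 12 h replicate 1 (0.233). Genes of the amino acid response, which adapts cells to amino acid shortage, were higher in 23 of 31 cases (median 0.04, adjusted camera p 0.0318). Of these 0 passed over all genes and 1, TRIB3, rose when adjusted over the list alone. With an estimated correlation the adjusted p was 0.602. The amino acid call was also lost without LacZ 6 h replicate 4 (adjusted p 0.0713), GPI-PLD 6 h replicate 3 (0.0962), LacZ 12 h replicate 1 (0.181) or 3 (0.0911), and GPI-PLD 12 h replicate 2 (0.152) or 4 (0.0679). Further members of that list were the stress transcription factor genes DDIT3 (0.23 ± 0.10) and CEBPB (0.13 ± 0.06) and the leucine transporter gene SLC7A5 (0.18 ± 0.08).

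TUBB2A was the 1 gene whose GPI-PLD effect differed between the times. Its signal was 2668 ± 119 in LacZ and 3474 ± 201 in GPI-PLD cells at 6 h, against 3456 ± 301 and 2416 ± 420 at 12 h (mean ± SD, 4 arrays per group). The difference of the log2 effects was -0.89 ± 0.15, or 1.85-fold, with an adjusted p of 0.0384 that ranged from 0.00169 to 0.196 over 27 alternatives, of which 17 lost the call. It was lost without LacZ 6 h replicate 2 (adjusted p 0.0696), 3 (0.0816) or 4 (0.117), GPI-PLD 6 h replicate 2 (0.0523), 3 (0.109) or 4 (0.164), LacZ 12 h replicate 1 (0.0773), 2 (0.164), 3 (0.0738) or 4 (0.0876), and GPI-PLD 12 h replicate 1 (0.133) or 3 (0.106). With time TUBB2A rose in LacZ cells (0.36 ± 0.11, adjusted p 0.0369) and fell in GPI-PLD cells (-0.53 ± 0.11, adjusted p 0.00184). EIF3L followed the same course, with mean signals of 12059 and 14784 at 6 h and 16456 and 11434 at 12 h in LacZ and GPI-PLD cells. It rose with time in LacZ (0.45 ± 0.10, adjusted p 0.0072) and fell in GPI-PLD cells (-0.36 ± 0.10, adjusted p 0.0285). Its difference of effects was -0.81 ± 0.15, with an adjusted p of 0.0548 that ranged from 0.0217 to 0.528 over the alternatives and passed in 4 of them.

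Differences of effect that did not pass included GUCA2A (-1.71 ± 0.42), CIDEB (-0.82 ± 0.20), ABAT (-0.68 ± 0.16), NDUFB8 (-0.54 ± 0.14), DYNLL1, a dynein light chain (-0.53 ± 0.12), and OS9, a lectin of protein quality control (-0.49 ± 0.12). COQ7, an enzyme of ubiquinone synthesis (0.66 ± 0.16), and TCEA1, a transcription elongation factor (0.46 ± 0.11), differed in the other direction. For ABAT another probe set (0.09 ± 0.15) and for NDUFB8 both others (0.18 ± 0.17 and 0.22 ± 0.33) had the opposite sign. As lists, oxidative phosphorylation differed between the times (45 of 61 members lower, median -0.10, adjusted camera p 0.00282), with 0 members over all genes and 3 that fell when adjusted over the list alone. With an estimated correlation its adjusted p was 0.466. Fatty acid and triglyceride synthesis (14 of 19 lower, median -0.20, adjusted camera p 0.00872) had 0 members over all genes and 1 that fell when adjusted over the list alone. Its adjusted p with an estimated correlation was 0.0950. Cytosolic ribosomal proteins (38 of 52 higher, median 0.08, 0 over all genes and 0 when adjusted over the list alone, adjusted camera p 0.0419) were led by RPL35A (0.43 ± 0.13) and RPL27A (0.46 ± 0.18), both of the large subunit. With an estimated correlation that adjusted p was 0.832. The ribosomal call was lost without LacZ 6 h replicate 2 (adjusted p 0.156) or 3 (0.539), GPI-PLD 6 h replicate 1 (0.0651), 2 (0.307) or 3 (0.207), LacZ 12 h replicate 1 (0.464) and GPI-PLD 12 h replicate 4 (0.663). Across all genes the log2 effects at 6 h and 12 h had a Pearson r of -0.109, within the -0.194 to 0.154 of 100 regroupings of the arrays.

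Stress response and cell cycle genes were among those that moved most between 6 h and 12 h in the cells of either virus. In LacZ cells CEBPB, a transcription factor of the stress and acute phase response, rose 4.09-fold (5803 to 23930; log2 2.03 ± 0.08, SE, 4 arrays per time, adjusted p 1.26e-13). DDIT4, an inhibitor of mTOR signalling, rose 4.08-fold (2285 to 9410; log2 2.03 ± 0.17) and SLC7A11, the cystine transporter gene, 4.03-fold (1211 to 5002; log2 2.01 ± 0.12). CYP1A1, an enzyme of xenobiotic metabolism, fell 4.03-fold (1538 to 357; log2 -2.01 ± 0.20), and the mitotic kinase gene AURKA fell 2.17-fold (9798 to 4501; log2 -1.11 ± 0.12). In GPI-PLD cells ATF3, a transcription factor of the integrated stress response, rose 4.49-fold (403 to 1984; log2 2.17 ± 0.18, adjusted p 1.01e-08), as did INHBE, a liver activin subunit (692 to 3308; log2 2.17 ± 0.13).

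Others that rose most in LacZ cells were PPP1R15A, which restores translation after stress (1.89 ± 0.18), VEGFA, an angiogenic growth factor (1.81 ± 0.13), CTH, an enzyme of cysteine synthesis (1.80 ± 0.16), ATF3 (1.76 ± 0.18) and INHBE (1.75 ± 0.13). In GPI-PLD cells they were DDIT3, which encodes the stress factor CHOP (1187 to 4380; 1.82 ± 0.14), SLC7A11 (1.78 ± 0.12), CTH (1.74 ± 0.16), ANGPTL8, a lipoprotein lipase regulator (270 to 1012; 1.73 ± 0.24), DDIT4 (1.72 ± 0.17) and CEBPB (7178 to 23413; 1.71 ± 0.08, adjusted p 5.58e-12). Those that fell most in LacZ cells included TXNIP, an inhibitor of thioredoxin (-1.23 ± 0.18), and the metal-binding metallothionein genes MT1F (-1.39 ± 0.16), MT1H (-1.38 ± 0.31), MT1X (7965 to 3250; -1.29 ± 0.15), MT1HL1 (-1.22 ± 0.32) and MT1E (-1.11 ± 0.17). In GPI-PLD cells MT1H (-1.63 ± 0.31), MT1X (8537 to 3136; -1.45 ± 0.15), MT1F (-1.35 ± 0.16), MT1HL1 (-1.34 ± 0.32), MT1E (-1.33 ± 0.17), CYP1A1 (1378 to 495; -1.38 ± 0.20), the mitotic kinesin gene KIFC1 (-1.43 ± 0.37) and the chromosomal passenger gene CDCA8 (-1.11 ± 0.16) fell most. The MT1HL1 call in LacZ cells was lost without LacZ 6 h replicate 1 (adjusted p 0.0606), 3 (0.0546) or 4 (0.0984) or LacZ 12 h replicate 1 (0.102) or 3 (0.0933). The KIFC1 call was lost without GPI-PLD 12 h replicate 1 (0.0595) or 3 (0.0543). In 20 comparisons of the genes named as moving most with their other bright probe sets, some made in both viruses, 1 differed in sign, for an AURKA probe set at 0.16 in LacZ cells. The other bright MT1X probe set stood at -0.21 ± 0.21 in LacZ and -0.52 ± 0.21 in GPI-PLD cells, a smaller difference than at the set named.

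With time 558 genes changed in LacZ cells, 295 up and 263 down (52.9% up), and 784 in GPI-PLD cells, 373 up and 411 down (47.6% up). Scaling the arrays to the same 75th percentile moved the LacZ split to 242 up and 390 down (38.3% up), and the GPI-PLD split to 352 and 414. At 2-fold or more the counts were 72 and 93. Across genes the log2 changes with time in the cells of each virus had a Pearson r of 0.417. Genes that rose in both numbered 183, against 13.6 expected from the separate counts, and 154 fell in both, against 13.3. Over all tested genes 63.9% had the same sign in both, and of 1003 genes called in either, 913 (91.0%) did, and the 2 genes called in opposite directions were TUBB2A and EIF3L.

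**Figure D3:**
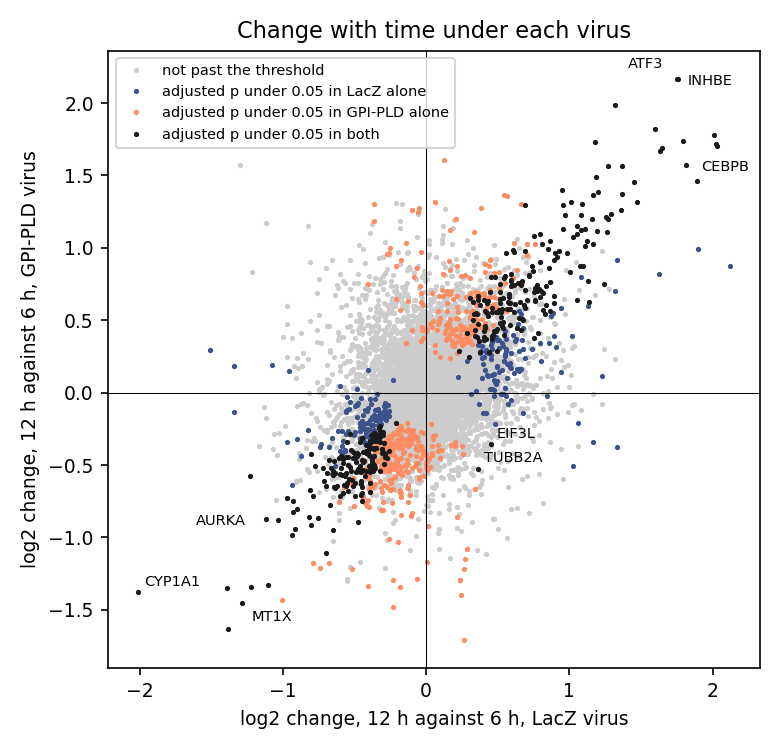
Log2 change from 6 h to 12 h in LacZ cells (horizontal) and in GPI-PLD cells (vertical) for all tested genes, coloured by call, 4 arrays per group, no error bars. Over all tested genes r was 0.417, and 183 genes were called up and 154 down in both viruses.

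Amino acid response and serine synthesis genes rose as a list in both viruses (31 tested, median 0.57 in LacZ and 0.62 in GPI-PLD cells). Of them 19 and 20 rose over all genes, and 24 and 26 when adjusted over the list alone. CEBPB, TRIB3 (1.29 ± 0.08 and 1.24 ± 0.08) and the transporter subunit gene SLC3A2 (1.11 ± 0.09 and 1.13 ± 0.09) led it. Its adjusted camera p was 2.39e-30 and 1.72e-29, and 5.17e-05 and 6.86e-05 with an estimated correlation. The unfolded protein response list (33 tested, median 0.37 and 0.45) had 15 risen and 1 fallen in LacZ and 16 risen in GPI-PLD cells, or 21, 1 and 17 when adjusted over the list alone. HERPUD1 of ER-associated degradation (1.65 ± 0.10 and 1.69 ± 0.10), the ER cochaperone gene DNAJB9 (1.37 ± 0.09 and 1.56 ± 0.09) and the ER chaperone gene HSPA5 (0.36 ± 0.08 and 0.64 ± 0.08) rose, and the translocon gene SEC61B fell in LacZ cells (-0.55 ± 0.11). The adjusted camera p of that list was 1.31e-18 and 1.26e-18, with 5.17e-05 and 6.86e-05 for an estimated correlation.

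Protein kinase C targets and immediate early genes rose with time (25 tested, median 0.85 and 0.64), 17 and 12 over all genes and 20 and 19 when adjusted over the list alone. Members included the survival gene IER3 (1.20 ± 0.09 and 1.39 ± 0.09), the growth factor response gene MYC (1.36 ± 0.12 in LacZ), the MAP kinase phosphatase gene DUSP1 (1.09 ± 0.10 in LacZ) and PHLDA1, a regulator of apoptosis (0.85 ± 0.08 and 0.99 ± 0.08, with other PHLDA1 probe sets at 0.25 ± 0.19 and 0.36 ± 0.22 in GPI-PLD cells). Its adjusted camera p was 1.01e-22 and 2e-18, and 5.17e-05 and 0.00015 with an estimated correlation. Oxidative stress and NRF2 targets rose too (27 tested, median 0.16 and 0.07), with 11 risen in each virus and 1 fallen in GPI-PLD cells over all genes. Adjusted over the list alone, 11 rose and 3 fell in LacZ and 12 rose and 2 fell in GPI-PLD cells. The glutathione synthesis genes GCLC (1.45 ± 0.10 in each virus) and GCLM (0.96 ± 0.15 and 1.29 ± 0.15) and the thioredoxin reductase gene TXNRD1 (0.96 ± 0.09 and 1.13 ± 0.09) rose, and the catalase gene CAT fell in GPI-PLD cells (-0.38 ± 0.08). The adjusted p with an estimated correlation was 0.0166 and 0.0236.

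Hypoxia response genes rose (27 tested, median 0.16 and 0.26), 6 in LacZ cells and 7, with 1 fallen, in GPI-PLD cells over all genes, and 8 with 1 fallen in each when adjusted over the list alone. STC2, a secreted glycoprotein (1.06 ± 0.13 and 1.15 ± 0.13), and BHLHE40, a clock repressor (1.12 ± 0.16 and 1.05 ± 0.16), led, and the glycolytic gene LDHA fell in GPI-PLD cells (-0.28 ± 0.07). The adjusted p with an estimated correlation was 0.00197 and 0.00313. The lists overlap, as VEGFA and DDIT4 of the hypoxia list are also in the unfolded protein response list. STC2 is also in the amino acid response list and IGFBP1 in the gluconeogenesis list. SLC7A11 belongs to the amino acid and NRF2 lists, and IER3 to the immediate early and NF-kappaB lists. The list calls are therefore not independent of each other. NF-kappaB and cytokine genes rose as well (16 tested, median 0.33 and 0.23), 3 and 5 over all genes, and 6 in each virus, with 2 fallen in LacZ cells, when adjusted over the list alone. The chemokine genes CCL20 (1.06 ± 0.10 and 1.09 ± 0.10) and CXCL8 (1.35 ± 0.25 in GPI-PLD) and the cytokine gene LIF (0.95 ± 0.20 and 1.40 ± 0.20) were among them. The adjusted p with an estimated correlation was 0.00701 and 0.00712.

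Cell cycle genes fell with time. Of 49 G2 and mitosis genes all 49 were lower at 12 h in LacZ cells (median -0.38, and -0.42 in GPI-PLD cells). Over all genes 20 and 25 fell, and 34 and 32 when adjusted over the list alone, among them the cyclin gene CCNB1 (-0.70 ± 0.09 and -0.65 ± 0.09), the securin gene PTTG1 (-0.81 ± 0.11 and -0.42 ± 0.11) and the topoisomerase gene TOP2A (-0.37 ± 0.08 and -0.54 ± 0.08). The adjusted camera p was 1.3e-20 and 1.85e-19, with 5.17e-05 and 6.86e-05 for an estimated correlation. Of 47 replication and S phase genes (median -0.31 and -0.53) 15 and 22 fell over all genes and 21 and 31 when adjusted over the list alone. GINS1 (-0.76 ± 0.10 and -0.86 ± 0.10) and MCM2 (-0.69 ± 0.10 and -0.56 ± 0.10) of the replicative helicase and the sliding clamp gene PCNA (-0.67 ± 0.11 and -0.78 ± 0.11) led. Their adjusted p with an estimated correlation was 0.000839 and 0.000355.

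Of 7 metallothioneins 6 fell in each virus over all genes and 6 when adjusted over the list alone (median -1.11 and -1.33), including MT2A (-0.93 ± 0.09 and -0.82 ± 0.09) and MT1G (-1.03 ± 0.17 and -0.88 ± 0.17). The remaining member, the brain form MT3, stood at -0.47 ± 0.35 and 0.62 ± 0.35. Several of these probe sets can read more than 1 family member. The list had an adjusted p of 0.00213 and 0.00595 with an estimated correlation. Oxidative phosphorylation genes fell (61 tested, median -0.21 and -0.27), 12 and 27 over all genes and 24 and 37 when adjusted over the list alone, with the complex I genes NDUFB4 (-0.42 ± 0.08 and -0.54 ± 0.08) and NDUFB3 (-0.43 ± 0.09 and -0.58 ± 0.09) and the cytochrome c oxidase genes COX6B1 (-0.42 ± 0.09 and -0.40 ± 0.09) and COX7B (-0.30 ± 0.08 and -0.50 ± 0.08). Their adjusted p with an estimated correlation was 0.0046 and 0.000369.

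**Figure D4:**
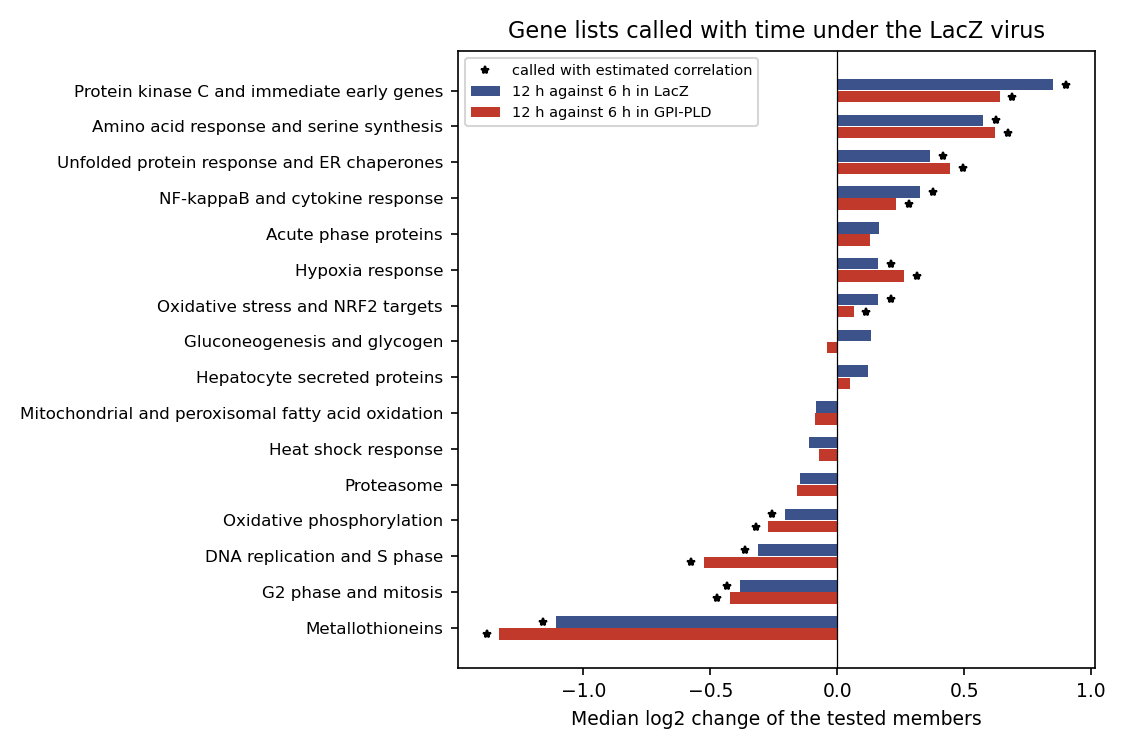
Median log2 change from 6 h to 12 h of the gene lists called in LacZ cells, shown for LacZ and GPI-PLD cells (4 arrays per group, no error bars), with a star where the adjusted p with an estimated correlation was under 0.05. The immediate early list stood at 0.85 and 0.64 and the metallothioneins at -1.11 and -1.33.

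Of 38 lists 16 were called with time in LacZ cells and 12 in GPI-PLD cells, and 10 in each with an estimated correlation. Proteasome genes, which degrade ubiquitinated proteins, fell (33 tested, 6 and 3 over all genes, 9 and 5 when adjusted over the list alone), with PSMA7 (-0.38 ± 0.08 in LacZ) and PSMA2 (-0.42 ± 0.08 in GPI-PLD). Their adjusted camera p was 7.35e-06 and 0.000407, and the adjusted p with an estimated correlation was 0.0982 and 0.216. Heat shock genes fell (19 tested, 4 and 5 over all genes and as many when adjusted over the list alone), with the chaperone genes HSPE1 (-0.37 ± 0.07 and -0.49 ± 0.07) and DNAJB1 (-0.39 ± 0.08 and -0.55 ± 0.08). Their adjusted camera p was 0.00236 and 0.0166, and the adjusted p with an estimated correlation was 0.0604 and 0.151. Hepatocyte secreted proteins were called up in LacZ cells (36 tested, 3 risen over all genes and 4 when adjusted over the list alone, adjusted camera p 0.0198), with the hyaluronan-linked protein gene ITIH3 (0.69 ± 0.12) and the protease inhibitor gene SERPINA3 (0.47 ± 0.09). The adjusted p with an estimated correlation was 0.18, and without LacZ 6 h replicate 4 the adjusted p was 0.101. Acute phase proteins, the liver's inflammatory plasma proteins, gave an adjusted camera p of 0.0237 in LacZ cells (18 tested, SERPINA3 the 1 risen over all genes and when adjusted over the list alone), and an adjusted p of 0.0524 with an estimated correlation. Without LacZ 6 h replicate 1 (0.0526) or LacZ 12 h replicate 3 (0.0511) the acute phase call was lost.

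Gluconeogenesis genes rose in LacZ cells (15 tested, 3 over all genes and 3 when adjusted over the list alone, adjusted camera p 0.0237), among them IGFBP1, an insulin-responsive binding protein (1.26 ± 0.17), the transaminase gene GOT1 (0.59 ± 0.08) and the mitochondrial PEP carboxykinase gene PCK2 (0.46 ± 0.09). The adjusted p with an estimated correlation was 0.0532. Fatty acid oxidation genes fell in LacZ cells (23 tested, 2 over all genes and 3 when adjusted over the list alone, adjusted camera p 0.0419), with the isomerase gene ECI2 (-0.36 ± 0.07). Their adjusted p with an estimated correlation was 0.258, and the call was lost without LacZ 6 h replicate 2 (adjusted p 0.0717) or 3 (0.0879) or LacZ 12 h replicate 4 (0.171).

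Single genes of GPI and lipid metabolism also moved with time. VLDLR, a lipoprotein receptor, rose in both viruses (1.01 ± 0.21 and 1.31 ± 0.21). PIGA, which starts anchor synthesis, rose in LacZ cells (0.83 ± 0.17, adjusted p 0.00265). In GPI-PLD cells its change was 0.54 ± 0.17 with an adjusted p of 0.0434, lost in 12 of 20 alternatives (0.0203 to 0.168), among them every single-array omission except GPI-PLD 6 h replicate 4. Those PIGA values were 0.109, 0.121 and 0.0531 without GPI-PLD 6 h replicates 1, 2 and 3, and 0.0925, 0.0816, 0.0540 and 0.0796 without GPI-PLD 12 h replicates 1 to 4. The complement regulator gene CD55 rose in GPI-PLD cells (0.97 ± 0.18). In LacZ cells its change was 0.62 ± 0.18, a call lost without LacZ 6 h replicate 1 (adjusted p 0.0762) or 4 (0.101) or LacZ 12 h replicate 1 (0.111) or 2 (0.108). The other bright CD55 probe set rose more in both viruses, by 1.22 ± 0.20 in LacZ and 1.62 ± 0.20 in GPI-PLD cells. The adhesion gene CEACAM5 rose in LacZ cells (0.87 ± 0.22, adjusted p 0.0138), but not without LacZ 12 h replicate 1 (0.0764), and its other probe set stood at -0.19 ± 0.34. In GPI-PLD cells DPM3 of the mannose donor synthase (-0.78 ± 0.19) and ELOVL6 (-0.52 ± 0.12) fell. The GPI anchor list was not called with time (adjusted p 0.631 in LacZ and 0.295 in GPI-PLD cells), nor were the GPI-anchored proteins (0.839 and 0.599). The latter had a median of -0.05 in LacZ cells but a mean of 0.00.

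Markers of other cell types gave no called list. The leukocyte, fibroblast and cholangiocyte lists had adjusted p values of 0.885, 0.591 and 0.378 with time in LacZ cells and 0.827, 0.534 and 0.823 between the viruses at 6 h. The 2 brightest markers of each type were, for bile duct cells, SPP1 (mean signal 19103) and SOX9 (7232), a matrix protein and a transcription factor. For leukocytes they were the lysozyme gene LYZ (9632) and the T cell receptor subunit gene CD3E (434), and for fibroblasts the smooth muscle actin gene ACTA2 (2476) and the collagen gene COL1A1 (774). For endothelial cells they were the receptor genes STAB1 (591) and PECAM1 (286), and for erythroid cells the globin genes HBB (480.1) and HBE1 (231). Of markers on the array 7 of 17 for leukocytes and 8 of 15 for fibroblasts passed the filter. For bile duct cells 6 of 11 did, for endothelial cells 3 of 13 and for erythroid cells 2 of 7. Below the filter lay PTPRC (mean signal 111) and NKG7 (17.8) of leukocytes and LUM (8.44) of fibroblasts, among others. So did CDH5 (20.2) of endothelial and KRT7 (103) of bile duct cells. Whether HepG2 cells themselves made the brighter marker transcripts was not tested.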

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

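The tests that split genes, unadjusted p values and preset-correlation lists and the GPLD1 interval test were chosen after seeing the results. So were the RNA integrity test of the GPI-PLD time calls, the reordered ratios and the smallest of 38 list p values. The other tests were written before.

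The largest pattern was the change from 6 h to 12 h, with 337 genes called in the same direction in both viruses. Array scaling by the authors is an unlikely cause, because 91.1% of these genes stayed called in both after quantile normalization. RNA integrity or labelling that differs between the times remains possible in LacZ cells. The outcome written beforehand for it was met, as only 39.8% stayed called in both with the GAPDH and ACTB 3' to 5' ratios as covariates. The median absolute log2 change of the 337 genes nevertheless went only from 0.58 to 0.57. In LacZ cells their median SE grew from 0.110 to 0.160 with the covariates and their median change went from 0.56 to 0.55. Lost calls there can come from the larger SE, so the test cannot decide. In GPI-PLD cells their median change went from 0.60 to 0.58 with an SE of 0.109. Of all time calls in GPI-PLD cells 93.0% were kept. The GAPDH ratio in GPI-PLD cells was 0.951 ± 0.0539 (SD) at 6 h and 0.974 ± 0.101 at 12 h (exact permutation p 0.771). The ACTB ratio was 1.33 ± 0.22 and 1.41 ± 0.25 (exact permutation p 0.543). For these cells the values argue against a difference that the 2 ratios track. The loss of calls shared by both viruses exceeded what most added covariates bring. Random reorderings of the ratios left a median of 73.0% of the genes. Fewer calls from any 2 added covariates could still not be excluded, because 5 of 100 reorderings left as few. Time in culture and time after infection stay open as untested.

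For the time contrasts random regrouping of the arrays is an unlikely source of the gene counts. Only 1 of 35 splits, the real one, reached 558 genes in LacZ and 1 of 35 reached 784 in GPI-PLD cells, with a highest other split of 1 gene each. At unadjusted p under 0.05 the same held, with 1 of 35 splits as large for 1634 genes in LacZ (highest other 815) and 1 of 35 for 1844 in GPI-PLD cells (highest other 898). It also held for lists with an estimated correlation, where 1 of 35 splits gave 10 lists in each virus and the highest other gave 0. For lists with the preset correlation chance cannot be excluded, as 3 of 35 splits gave 16 or more in LacZ (highest other 17) and 5 of 35 gave 12 or more in GPI-PLD cells (highest other 12). In all these comparisons 1 of 35 is the smallest share possible. Splits that mix the times also carry the time difference into the spread, which can lower their counts. Differences between cultures or batches cannot be excluded, because the labels do not give them.

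The fatty acid and triglyceride synthesis list was higher in GPI-PLD cells at 6 h with the preset correlation (adjusted p 0.0121), but was not called with an estimated correlation (0.0787) or without LacZ 6 h replicate 2 (0.0787). The other members argue against 1 gene, DGAT1, carrying the direction of the list. Without DGAT1 15 of 18 members were higher, with a median log2 difference of 0.13. The unadjusted camera p was then 0.00423, under the bound written beforehand. That bound left out the adjustment over the lists, with which the camera p was 0.161, so the call itself was lost without DGAT1. Random regrouping of the arrays gave this list so small a p in 1 of 35 splits, the real one (0.000319, with 0.00346 the smallest other). The smallest of 38 list p values being picked may account for the call, as 18 of 35 splits gave some list a p as small. DGAT1 itself was low in LacZ cells at 6 h (211), against 516 in LacZ cells at 12 h and 499.7 in GPI-PLD cells at 12 h.

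GPLD1 signals were similar between the viruses. A GPLD1 transcript from the virus that raises signal + 63 by 2-fold or more is unlikely for the pair of brighter probe sets alone. There the highest upper end of the 95% interval was 1.74. The pseudocount of 63 compresses fold changes, so the bound on signal alone is higher and was not computed. The dim probe sets do not exclude such a transcript, as their upper ends at 6 h reached 2.44 and 2.07. Probe sets that lie outside the part of GPLD1 the virus carries cannot be told apart from absent expression, because the place of 0 probe sets is known.

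For the virus contrasts, chance could not be excluded wherever the real count was above 0. At 6 h 14 of 35 splits had 376 or more genes at unadjusted p under 0.05 (highest other 603) and 21 of 35 called 1 list or more (highest other 9). At 12 h 2 of 35 had 584 or more genes at unadjusted p under 0.05 (highest other 660) and 23 of 35 called 1 list or more (highest other 4). Averaged over both times 56 of 100 had 340 or more genes at unadjusted p under 0.05 (highest other 645) and 38 of 100 called 2 lists or more (highest other 10). For the difference of the effect between the times 5 of 100 splits had 1 gene or more (highest other 3), 6 of 100 had 610 or more at unadjusted p under 0.05 (highest other 675) and 24 of 100 called 3 lists or more (highest other 7). Splits that called 9, 10 and 7 lists could follow a structure of the samples other than virus, or gene correlation above the preset 0.01, since with an estimated correlation the highest other splits called 0, 2 and 0.

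A real count of 0 is reached by every split, so those comparisons decide nothing: 35 of 35 for genes at 6 h and 35 of 35 at 12 h (highest other 1 each), and 100 of 100 averaged (highest other 0). The same holds for lists with an estimated correlation, at 35 of 35 splits at 6 h and 35 of 35 at 12 h (highest other 0 each), 100 of 100 averaged (highest other 2) and 100 of 100 between the times (highest other 0).

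The GPI-PLD effect differed between 6 h and 12 h in TUBB2A (adjusted p 0.0384) and in the fatty acid (0.00872), ribosomal protein (0.0419) and oxidative phosphorylation lists (0.00282) with the preset correlation. With an estimated correlation all 3 list calls were lost (adjusted p 0.0950, 0.832 and 0.466).

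Of 628 groups of 4 arrays examined for 1 array far from the other 3, 34 were past the critical gap ratio of the Dixon test, where 31.4 arise because chance flags about 1 in 20 groups. Whole-array 75th percentiles were low in LacZ 6 h replicate 3 (1025.7 against 1069.7 to 1075.4, ratio 0.885) and GPI-PLD 6 h replicate 4 (1059 against 1082.5 to 1085.1, 0.900). For GPLD1, one dim probe set read 46 against 15.7 to 20.8 in LacZ 6 h replicate 3 (0.832) and another read 110.8 against 7.8 to 22.5 in LacZ 6 h replicate 2 (0.857). LacZ 6 h replicate 2 also stood apart for STXBP5L (0.910), SART3 (0.839), VAV2 (0.830), ACACA (0.946) and COL1A1 (0.832), replicate 1 for DDIT3 (0.960) and replicate 4 for COX7B (0.849). LacZ 12 h replicate 2 stood apart for TUBB2A (3904 against 3268 to 3354, ratio 0.864), PLAAT2 (0.871), TCEA1 (0.862) and RPL27A (0.846), replicate 3 for ABAT (0.898), and replicate 4 for HOXC11 (0.930), SART3 (0.894) and SPP1 (0.861). GPI-PLD 6 h replicate 1 did so for SEC61B (0.943), SERPINA3 (0.843) and STC2 (0.870), replicate 2 for PECAM1 (0.911), replicate 3 for VAV2 (0.936) and BHLHE40 (0.847), and replicate 4 for SARS1 (0.897) and TOP2A (0.991). GPI-PLD 12 h replicate 4 did so for SART3 (0.830), OS9 (0.865), APOC1 (0.844), CD55 (0.884) and SNRPD3 (0.838), and replicate 1 for GCLM (0.987) and HSPA5 (0.940).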

How the results depend on the processing

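The omission of GPI-PLD 12 h arrays 2 and 4 together was the 1 alternative chosen after seeing the results, while the others were set before the data were examined. No paired analysis was possible because the labels give no replicate numbers.

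For the difference of the virus effect between the times, the 1 gene of the first analysis became 0 with quantile normalization, 0 with 75th percentile scaling, 0 without a filter, 0 with all probe sets and 0 with eBayes without trend and robust. It became 2 with 4 times the pseudocount, 2 with the 60th percentile filter and 2 on omitting both GPI-PLD 12 h arrays. Virus genes became 2 at 6 h with eBayes without trend and robust and 3 at 12 h on omitting both arrays. Lists called at 12 h became 3 with quantile normalization and 2 on omitting both arrays, averaged lists became 1 with quantile normalization, and lists differing between the times became 1 on omitting both arrays. With an estimated correlation lists became 0 at 6 h, 0 at 12 h, 0 averaged, 0 between the times and 10 for time in LacZ.

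One gene result was reversed: NDUFA2 with time in GPI-PLD cells, -0.63 in the first analysis, was 0.16 with the mean of its probe sets (adjusted p 0.786). The cause was not tested.

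With 1 array left out in turn, virus genes ranged from 0 to 0 at 6 h, 0 to 2 at 12 h, 0 to 0 averaged and 0 to 3 between the times. The lists ranged from 0 to 3, 1 to 3, 0 to 4 and 2 to 3. Time genes ranged from 390 (without LacZ 12 h replicate 2) to 531 in LacZ and from 543 (without GPI-PLD 6 h replicate 3) to 735 in GPI-PLD cells, with 15 to 16 and 12 to 13 lists. GPLD1 at its brighter _at probe set ranged from -0.44 to -0.11 at 6 h and from 0.02 to 0.34 at 12 h. Over the other alternatives time genes ranged from 417 to 761 in LacZ and from 601 to 1002 in GPI-PLD cells, and the correlation of the virus effects from -0.155 to -0.088.

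Signal over background limits the fold changes of dim genes, which a pseudocount compresses where one is added.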

Other observations

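All gene groups of the first paragraph and the unfolded protein response tests were chosen after seeing the results.

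Among groups picked after their values were seen, for which no group p is given, the cytosolic tRNA synthetases charge tRNAs and partly belong to the amino acid response. With time 6 of 16 rose in each virus (median 0.19 in LacZ and 0.31 in GPI-PLD cells). CARS1 (0.87 ± 0.09 and 0.77 ± 0.09), GARS1 (0.75 ± 0.11 and 0.84 ± 0.11) and SARS1 (0.65 ± 0.08 and 0.63 ± 0.08) were among them. Of 25 genes of the snRNP and LSm families, most of which serve splicing, 9 and 11 fell (median -0.32 and -0.29), with LSM3 (-0.93 ± 0.11 and -0.75 ± 0.11), SNRPD3 (-0.55 ± 0.11 and -0.62 ± 0.11) and SNRPG (-0.46 ± 0.08 and -0.55 ± 0.08). Of 49 mitochondrial ribosomal protein genes 4 and 9 fell (median -0.14 and -0.21), with MRPL18 (-0.53 ± 0.09 and -0.39 ± 0.09). Of 20 autophagy genes 5 and 6 rose and 1 fell in GPI-PLD cells (median 0.20 and 0.17), with the receptor genes SQSTM1 (0.86 ± 0.13 in each) and TAX1BP1 (0.41 ± 0.09 and 0.64 ± 0.09, with another probe set at -0.02 ± 0.37 in GPI-PLD cells) and MAP1LC3B (0.69 ± 0.10 and 0.98 ± 0.10), while GABARAPL2 fell in GPI-PLD cells (-0.32 ± 0.08).

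The rise of unfolded protein response genes could reflect mainly the branch shared with amino acid shortage. In that case members shared with the amino acid response list rise more than the other members, and this was not met in both viruses: the higher exact permutation p was 0.0916. The test cannot decide on the branch, because sharing was read from list membership alone. PPP1R15A (1.89 in LacZ cells), VEGFA (1.81 in LacZ cells) and DDIT4, which rose strongly, were counted with the other members. Genes of a list are also not independent replicates. The 4 shared members had a mean log2 change of 1.08 ± 0.45 (SD) against 0.50 ± 0.66 for the other 29 in LacZ cells (exact permutation p 0.0916), and 1.18 ± 0.50 against 0.50 ± 0.59 in GPI-PLD cells (0.0296). A version with members picked by hand was run first and set aside as circular. Deciding between the branches would need measurements of the activity of each branch at both times, which these arrays do not give.

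GPI-PLD cells had a median array signal of 323 ± 10.9 at 6 h and 358 ± 16.4 at 12 h (exact permutation p 0.0286, the smallest possible, adjusted 0.343 over 24 tests). In LacZ cells the 75th percentile of signal was 1060.3 ± 23.2 at 6 h and 1098.7 ± 9.68 at 12 h (exact permutation p 0.0286, adjusted 0.343), and ribosomal RNA probe sets had a mean log2 signal of 8.28 ± 0.86 and 9.20 ± 0.24 (exact permutation p 0.0857, adjusted 0.343). GAPDH 3' to 5' ratios in LacZ cells were 0.913 ± 0.0364 and 0.999 ± 0.0609 (exact permutation p 0.0571, adjusted 0.343). The 2 GPI-PLD 12 h arrays furthest from their group were replicate 2 on the third component (score 30.2) and replicate 4 on the fourth (-28.3).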
